A study of Homo sapiens with 42 samples.

How the data were processed

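TC28a2 cells, non-transduced or transduced with adenovirus carrying EGFP or KLF4, were sampled without and with IL-1β, in 6 groups of 7 libraries (42 in all). Per the labels' protocols, total RNA was isolated with a Direct-zol RNA MicroPrep kit and libraries were made with a Twist Bioscience kit for high-throughput RNA-seq, then in early access; the design text names the assay as DRUG-seq. Groups and replicate numbers were taken from the sample titles. The dose and duration of IL-1β, the time after transduction and whether replicates were separate cultures are not given in the sources used here. Per the submitters' processing notes, the tools were UMI-tools, STAR 2.6.1d, featureCounts 1.6.4 and DESeq2 1.20.0 with the genome build GRCh38; their roles, settings, strand handling and annotation release are not given in the sources used here.

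The authors deposited a table of whole-number counts per gene for the 42 libraries, and a table of TPM (length-normalized transcript abundance) for the same libraries, made by the authors in a way not given in the sources used here. Each table lists 60623 genes by Ensembl identifier and symbol. The deposited counts were the basis of all main results. The deposited TPM values, which are not a rescaling of those counts, served only for an alternative. Each count column correlated best with the TPM column of the same library in 42 of 42 libraries. The number of per-sample columns left unused was 0. Gene coordinates are those of GENCODE v44 for GRCh38, with 60295 of 60623 identifiers matched, and give the span of the whole gene; a table of gene counts does not say in which exon or UTR the reads lay.

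Genes were tested with edgeR 4.0.16 (quasi-likelihood F-test; TMM normalization; filterByExpr by group with a minimum count of 10, which kept 13239 genes) in one model of the 6 group means over all 42 libraries, with 36 residual degrees of freedom and a common biological coefficient of variation of 0.241. Contrasts gave KLF4 against EGFP cells without and with IL-1β, the response to IL-1β in EGFP, non-transduced and KLF4 cells, the difference between the responses of KLF4 and EGFP cells, and EGFP against non-transduced cells without and with IL-1β. P-values were adjusted by Benjamini-Hochberg over the tested genes of each contrast, and a gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the root of its F statistic. CPM values are means over libraries of counts scaled by TMM library size, with the SD over 7 libraries; the fitted fold change weights libraries by depth and can differ from the ratio of these means. For a gene without a count in one group, the fold is a lower bound against 3 counts over that group, and with 1 to 3 counts it is a ratio of summed counts with an exact binomial 95% interval. Intervals and bounds cover counting error only; UMI-tools is among the tools the submitters name, but how UMIs entered the counts is not given in the sources used here.

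A set of 24 gene lists was fixed: cartilage matrix, hypertrophy and mineralisation, matrix-degrading enzymes, protease inhibitors, NF-κB and IL-1 response, interferon response, S phase, G2 and mitosis, p53 targets and growth arrest, KLF and SP family, epithelial, endothelial, immune cell, pluripotency, collagens and fibrous matrix, unfolded protein and amino acid stress, NRF2, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded, FOXO and autophagy, Wnt, BMP and TGF-β pathways, and ribosomal proteins. Lists with at least 4 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Some genes stand in more than one list. The groups, contrasts, lists, tests, the rule for named genes and most alternatives were chosen before the data were examined.

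Genes were named by a rule. It takes 20 landmark genes of KLF biology, cartilage and IL-1 signalling. It also takes the called genes with the largest changes in each direction, 8 each for both comparisons of KLF4 with EGFP and for IL-1β in EGFP cells and 4 each elsewhere. These needed at least 20 CPM in the higher group and all 7 libraries of one group beyond the median of the other. Last, it takes up to 4 called members with the smallest p-values of each list that was called or had at least 3 called members. The text names a subset of these genes. IL1R1, IL1RAP, MYD88, IRAK1, TRAF6, HBB, KRT5, KRT14 and KRT1, given under the further observations, were chosen for tests of explanations and lie outside the rule.

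The whole procedure was tested on simulated counts for 13239 genes with 200 changed genes, a further list of genes raised 1.5-fold, and no other difference. For KLF4 against EGFP with IL-1β it recovered 84.8% of 4-fold, 65.7% of 2-fold and 17.9% of 1.5-fold changes, with 6.87% false among its calls. For IL-1β in EGFP cells these shares were 87.9%, 53.7% and 23.9%, with 4.1% false, in non-transduced cells 93.9%, 64.2% and 17.9%, with 3.65% false, and in KLF4 cells 84.8%, 58.2% and 22.4%, with 4.76% false. Changes under 2-fold were therefore often missed in the simulation. Calls of the list raised 1.5-fold were not counted as false. The simulation held no difference between replicate sets or prefixes, and far fewer changed genes than were called for KLF4. Its shares may therefore not carry over to these data.

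Library totals ran from 379647 to 8950133 counts; 5 libraries lay under the low-depth limit of 977736.5, set relative to the median, 3 of them the EGFP libraries without IL-1β of replicates 1 to 3, so leaving them out also removes that replicate set from the group. A gene at 1 CPM had under 1 count on average in the smallest library, so levels near 1 CPM rest on the deeper libraries. Pairs of libraries within a group differed far beyond counting noise (chi-square per gene of 3.25 or more), so none was treated as a duplicate. Replicate numbers were checked for pairing by the correlation of deviations from the group means over the 3042 genes with a mean log2 CPM over 6. Every same-numbered pair exceeded the limit of 0.1 for IL-1β in EGFP (lowest 0.13), non-transduced (0.40) and KLF4 cells (0.11) and for EGFP against non-transduced cells without (0.40) and with IL-1β (0.28), but not for KLF4 against EGFP without (0.00) or with IL-1β (0.03). The mean correlation was 0.40 for equal numbers, 0.41 for other numbers of the same set (replicates 1 to 3, or 4 to 7) and −0.40 across the sets, so the pairing comes from the sets and not from the single number. Over all 13239 tested genes, a check added later, only both comparisons of EGFP with non-transduced cells passed. The smaller gene set was written into the first check, which printed the correlations together with the blocked counts; a change to all tested genes was then planned, and the smaller set was kept after the blocked counts had been seen.

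Alternatives were edgeR with DESeq2 size factors, DESeq2 1.42.0, limma on log2(TPM + 1), no filter and a laxer filter on low counts, the replicate number as a block, the library-name prefix as a term, libraries of one prefix only, only the groups compared, libraries under the low-depth limit left out, all libraries thinned to at most 1012428 counts, non-transduced cells as the control, KLF4 left out of the counts, each library left out in turn, a preset against an estimated correlation, and IL-1β genes limited to those changed at least 2-fold. In the thinning, called one total per library below, the 5 libraries under the low-depth limit kept their smaller totals. Added after the data were seen were a term for replicates 1 to 3 against 4 to 7, and either set alone. The result for 1 further gene is not reported here, though it is counted among the values of named genes under these alternatives. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15, and tests were run under R 4.3.3. Reads, the vector sequences and protein levels were not analysed here.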

Results

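Transcript levels were measured by DRUG-seq, a 3′-end RNA sequencing method with unique molecular identifiers (UMIs), in TC28a2 cells, an immortalised line of human chondrocytes, the cells of cartilage. Cells had received no virus, an adenoviral vector carrying EGFP (enhanced green fluorescent protein, the vector control) or an adenoviral vector carrying KLF4, a zinc finger transcription factor of the Krüppel-like family. Each state was sampled without and with interleukin-1β (IL-1β), a cytokine that drives cartilage breakdown and joint inflammation. This gave 6 groups of 7 libraries. The series concerns KLF4 and its relative KLF2 as regulators of cells of the joint and of inflammatory and tissue-degrading signals in osteoarthritis.

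The 42 libraries held between 379647 and 8950133 counts, with a median of 2933209.5. Group medians without IL-1β were 3244359 counts in non-transduced, 1012428 in EGFP and 3383492 in KLF4 cells, and with IL-1β 2872169, 3058850 and 2246695. Of 60623 listed genes, 33099 had a count and 13239 had enough counts to be tested. The mean share of counts in mitochondrially encoded transcripts lay between 1.85% and 2.19% in the 6 groups. Libraries of replicates 1 to 3 and of replicates 4 to 7 stood apart in all 6 groups along the first component of the deviations from the group means, which held 56.8% of that variation over the 3042 genes with a mean log2 CPM over 6 and 22.5% over all 13239 tested genes. The library names also carry a prefix (1, 2 or 3) that nearly follows the groups. All KLF4 libraries without IL-1β have prefix 2, while 6 of the 7 matching EGFP libraries have prefix 1 and replicate 7 has prefix 2. All KLF4 libraries with IL-1β have prefix 3, as have 5 of the 7 matching EGFP libraries. The labels do not say what the prefix or the replicate number stands for, so counts of called genes within prefixes and within replicate sets are given beside the pooled ones. Nothing says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

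**Figure D1:**
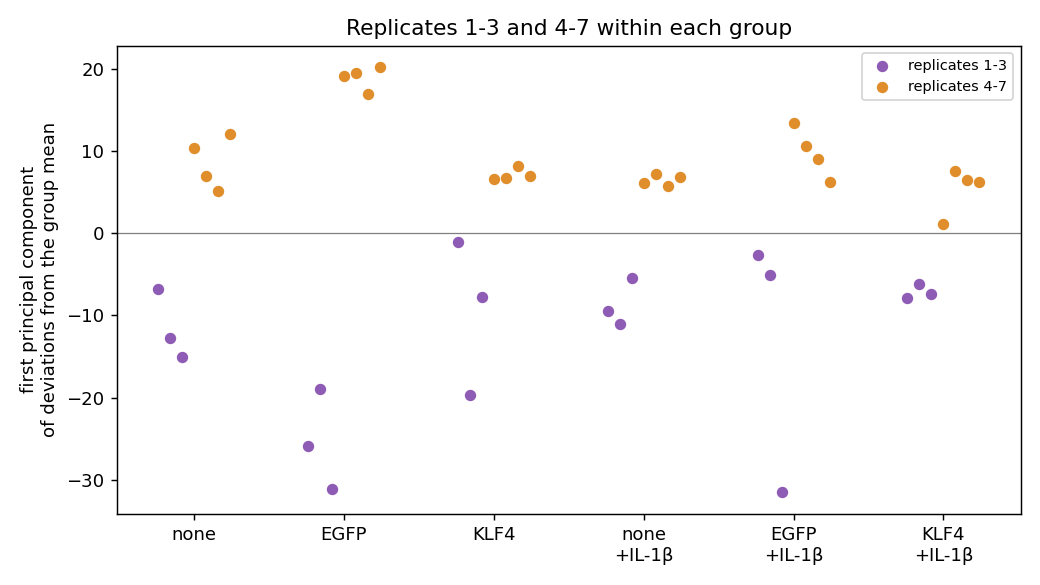
First principal component of each library's deviation from its group mean (vertical axis, log2 CPM units) for the 6 groups (horizontal axis); each point is a library, coloured by replicates 1 to 3 or 4 to 7. In each of the 6 groups all libraries of replicates 4 to 7 lie above all libraries of replicates 1 to 3.

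KLF4 itself (ENSG00000136826, chromosome 9, 107484852 to 107490482 in GRCh38) was read first, as a check of the labels. Its mean level was 8792 ± 719 CPM (the count as a share of the TMM-scaled library total, in the usual unit; mean ± SD, n = 7) in KLF4-transduced cells without IL-1β and 8689 ± 1090 CPM with it. EGFP cells had 4.76 ± 4.91 and 5.12 ± 3.08 CPM, and non-transduced cells 3.95 ± 1.71 and 1.96 ± 1.09 CPM. The lowest KLF4-transduced library had 7115 CPM. Reads of the transgene and of the native gene cannot be told apart in a table of gene counts. KLF2 had group means between 8.10 and 11.7 CPM and was not called in either comparison of KLF4 with EGFP cells (log2 0.35, SE 0.31, adjusted p = 0.342 without IL-1β; log2 0.51, SE 0.30, adjusted p = 0.132 with it), though with the library-name prefix as a term it was called higher under IL-1β (log2 0.73, adjusted p = 0.0391).

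**Figure D2:**
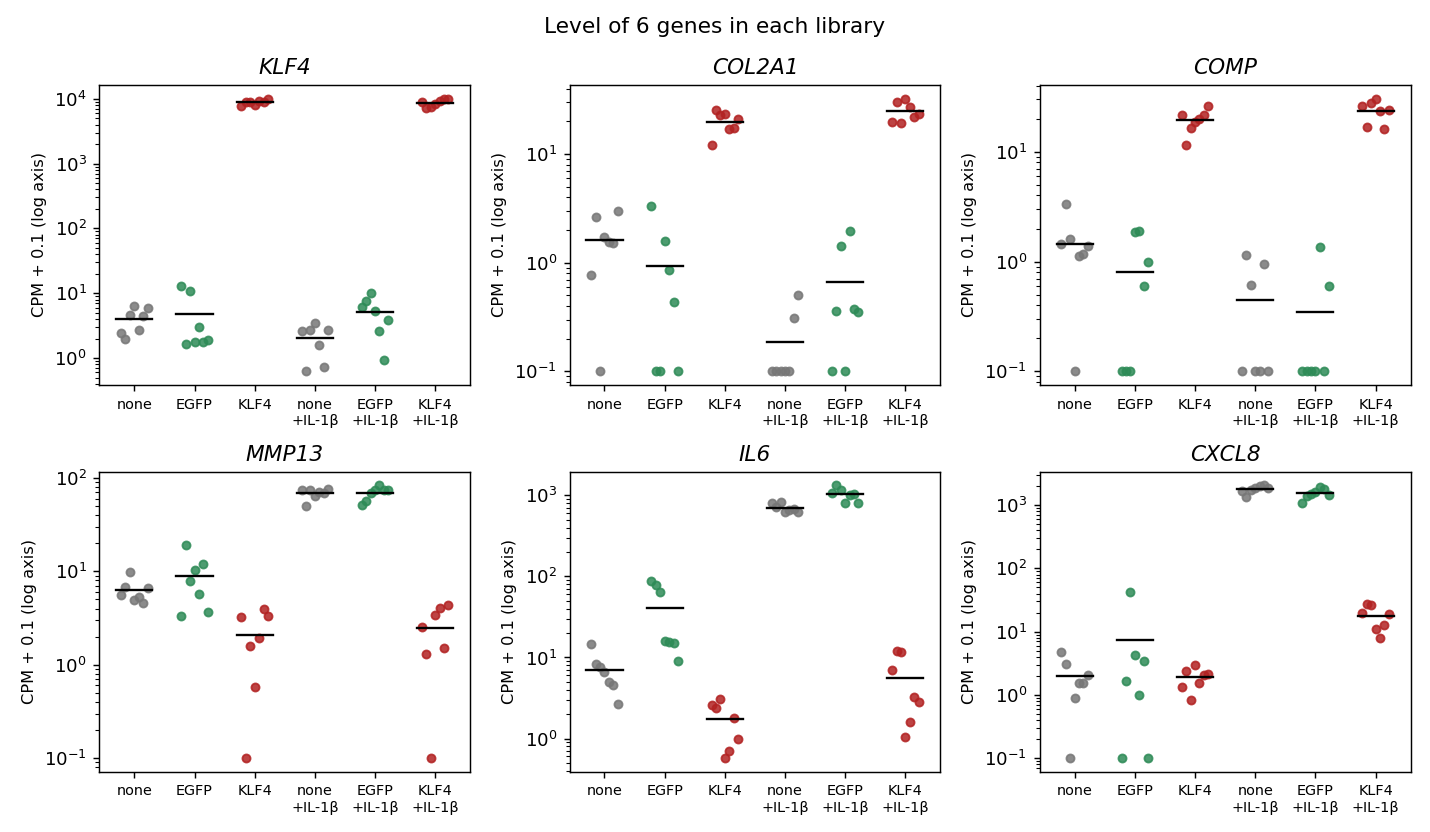
Levels of KLF4, COL2A1, COMP, MMP13, IL6 and CXCL8 (vertical axis, CPM + 0.1, log scale) in non-transduced, EGFP and KLF4 cells without and with IL-1β; each point is a library and each horizontal bar a group mean. KLF4 lies at 7115 CPM or more in all libraries with the KLF4 vector, COL2A1 and COMP are higher there, and MMP13, IL6 and CXCL8 with IL-1β are lower there than in EGFP cells.

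The first comparison asks what KLF4 does to unstimulated chondrocytes, against the EGFP vector. Genes of stratified epithelium rose strongly. KRT6A, a keratin of hair follicles and wounded skin (ENSG00000205420, chromosome 12, 52487176 to 52493257), was at 2381 ± 271 CPM in KLF4 cells (n = 7) and had no count in EGFP cells, a rise of at least 20380-fold against a floor of 3 counts over the group. KRT17 reached 3752 ± 445 CPM from 9.44 ± 4.88 (450-fold), KRT16 1014 ± 178 from 0.687 ± 1.14, and JUP (plakoglobin, a junction protein) 638 ± 89.1 from 31.5 ± 11.3. CDSN (corneodesmosin) rose at least 4232-fold to 509 ± 117 CPM. FLG (filaggrin, of the cornified layer) rose from 1 count to 358 ± 87.6 CPM, a ratio of 9928 with a 95% counting interval of 1781 to 392200. Reads of KRT6A may be shared with KRT6B and KRT6C, and those of KRT16 and KRT17 with each other and their pseudogenes, so the level of each single keratin is uncertain. Of 38 tested members of the epithelial list, 34 rose and 1 fell (35 and 1 adjusted over the list alone), with a median log2 change of 4.26 (limma's camera, adjusted p = 4.96e-16).

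Markers of other cell types with enough counts to be tested mostly rose too. A marker silent in EGFP and non-transduced cells passed the count filter only through the KLF4 libraries, so its direction was fixed in advance. For such members neither the share that rose nor camera's p is independent support, in any list and with IL-1β too. Of 8 tested immune cell markers 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00111, adjusted p = 0.0731 with an estimated correlation). CD52, a lymphocyte surface protein, went from no count to 151 ± 81.4 CPM (at least 1022-fold), and TYROBP, a myeloid adaptor, from no count to 20.9 ± 12.3 (at least 138-fold). Of 13 endothelial markers 11 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.00114), among them the tight junction gene CLDN5 at 55.8 ± 38.5 against 0.274 ± 0.618 CPM, the thrombin receptor THBD (12.2-fold) and the VEGF receptor FLT1 (6.37-fold). The 6 tested pluripotency genes went both ways, 3 higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.727). Further genes without a count in EGFP cells were HBA2 (alpha globin, 439 ± 174 CPM, at least 3223-fold), S100P (430 ± 180, at least 3053-fold), the hormone precursor TRH (356 ± 44.7, at least 3024-fold) and the potassium channel gene KCNJ18 (454 ± 87.8, at least 3711-fold). HBA2 is nearly identical to HBA1, and KCNJ18 to KCNJ12, so both are uncertain as to which copy the reads came from.

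Cartilage genes rose as well. Type II collagen, COL2A1 (ENSG00000139219, chromosome 12, 47972967 to 48004554), rose 22.7-fold, from 0.827 ± 1.19 to 19.8 ± 4.70 CPM (log2 4.51, SE 0.44, adjusted p = 1.77e-12). COMP, a cartilage matrix glycoprotein (ENSG00000105664, chromosome 19, 18782773 to 18791305), rose 16-fold to 19.3 ± 4.59 CPM (SE 0.46 on the log2 scale, adjusted p = 1.99e-10). PRG4, the joint lubricant lubricin (ENSG00000116690, chromosome 1, 186296279 to 186314567), had no count in EGFP cells and 36.9 ± 13.4 CPM in KLF4 cells, a rise of at least 349-fold. COL11A2 rose 129-fold to 296 ± 51.1 CPM, COL9A3 20.8-fold, the proteoglycan gene VCAN 8.47-fold, and PRELP had 37.5 ± 7.17 CPM against 1 count, a ratio of 1031 (185 to 40774). ACAN (aggrecan, the main cartilage proteoglycan) rose 6.59-fold to 8.39 ± 3.71 CPM, and the chondrocyte transcription factor SOX9 1.29-fold, from 60.7 ± 13.4 to 82.7 ± 16.3 CPM (adjusted p = 0.0435). COL11A1 (33 counts in KLF4 and 0 in EGFP cells) and CILP (4 and 13 counts) were too low to test. Of 20 tested members of the cartilage list 16 rose and 3 fell (16 and 3 adjusted over the list alone), with a median of 2.67 (camera adjusted p = 2.19e-05). Of 13 hypertrophy and mineralisation genes 8 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.0965). The phosphatase gene PHOSPHO1 rose 59.5-fold, the growth plate signals PTHLH 36.4-fold and IHH 53.9-fold.

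Protease inhibitors rose, while matrix-degrading enzymes went both ways. TIMP1, an inhibitor of matrix metalloproteinases (ENSG00000102265, chromosome X, 47582408 to 47586789), rose 28.9-fold to 4509 ± 811 CPM from 160 ± 58.3, TIMP2 4.37-fold to 1026 ± 150 CPM, and SLPI, a secreted inhibitor of leukocyte proteases, 180-fold to 655 ± 258 CPM. Of 13 tested inhibitors 9 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.00137, adjusted p = 0.0731 with an estimated correlation). Of 31 enzymes 14 rose and 10 fell (14 and 10 adjusted over the list alone; camera adjusted p = 0.245). The membrane-type metalloproteinases MMP15 (15.1-fold to 240 ± 34.2 CPM) and MMP14 (6.39-fold), the lysosomal protease CTSD (6.69-fold) and the aggrecanase ADAMTS4 (69-fold, to 15.9 ± 4.38 CPM from 0.0897 ± 0.154) were higher. The collagenase MMP13 (ENSG00000137745, chromosome 11, 102942995 to 102955732) was 4.04-fold lower, at 2.00 ± 1.47 against 8.74 ± 5.53 CPM, the aggrecanase ADAMTS5 4.29-fold lower at 0.511 ± 0.933 against 2.14 ± 2.48 CPM, and the collagenase MMP1 5.36-fold lower, from 38.9 ± 43.6 CPM in EGFP cells (adjusted p = 0.0417). MMP3 was not called (log2 −0.98, SE 1.07, adjusted p = 0.442).

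Inflammatory genes and fibrous matrix genes were mixed or lower. The monocyte chemokine CCL2 (ENSG00000108691, chromosome 17, 34255274 to 34257208) was 254-fold lower, at 0.228 ± 0.401 against 75.4 ± 38.1 CPM, and the leukocyte adhesion receptor VCAM1 (ENSG00000162692, chromosome 1, 100719742 to 100739045) 161-fold lower, at 0.558 ± 0.446 against 119 ± 32.2 CPM. The cytokine IL6 fell 22.3-fold to 1.63 ± 0.993 CPM, whereas the antibacterial protein gene LCN2 (730-fold) and complement C3 (52.5-fold) were higher. The chemokine CXCL8 was 2.48-fold lower (adjusted p = 0.039), with only 3 of the 7 KLF4 libraries below the EGFP median. PTGS2 (adjusted p = 0.31) and LIF (adjusted p = 0.0765) were not called, and NOS2 had 0 counts in KLF4 and 9 in EGFP cells. Of 54 genes of the NF-κB and IL-1 response list 15 rose and 23 fell (17 and 23 adjusted over the list alone; camera adjusted p = 0.32). Of 48 interferon response genes 12 rose and 18 fell (12 and 18 adjusted over the list alone; camera adjusted p = 0.701; median −0.29, mean 0.04). Of 38 collagen and fibrous matrix genes 13 rose and 19 fell (13 and 19 adjusted over the list alone; camera adjusted p = 0.00272, adjusted p = 0.214 with an estimated correlation). Fibronectin, FN1, fell 6.37-fold from 1547 ± 306 to 242 ± 42.1 CPM, THBS1 7.72-fold, TGFBI 5.49-fold and periostin, POSTN, 26.5-fold. The transcription factor MSC (47-fold) and NREP (73.9-fold) were among the largest falls.

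Mitotic genes were lower and growth arrest genes higher. Of 50 G2 and mitosis genes 44 fell and 1 rose (45 and 1 adjusted over the list alone; camera adjusted p = 1.17e-15), such as the cyclins CCNB1, at 70.4 ± 20.2 against 252 ± 35.9 CPM, and CCNA2 (2.83-fold lower). Of 44 S phase genes 18 fell and 5 rose (17 and 5 adjusted over the list alone; camera adjusted p = 0.00719, adjusted p = 0.0984 with an estimated correlation), MCM2 by 2.58-fold. Of 31 p53 target and growth arrest genes 24 rose and 3 fell (24 and 3 adjusted over the list alone; camera adjusted p = 2.12e-06). They include the cyclin-dependent kinase inhibitors CDKN1C (ENSG00000129757, chromosome 11, 2883213 to 2885775), which rose 41-fold to 1043 ± 255 CPM, and CDKN1A (4.21-fold to 1047 ± 55.9 CPM), and SFN, 14-3-3 sigma (128-fold). Of 28 FOXO and autophagy genes 17 rose and 2 fell (17 and 2 adjusted over the list alone; camera adjusted p = 0.00301), such as MAP1LC3B (4.65-fold) and ATG16L1 (9.19-fold).

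Of 75 ribosomal protein genes 72 fell (72 adjusted over the list alone), with a median of −1.53 (camera adjusted p = 1.57e-22, adjusted p = 0.207 with an estimated correlation). RPL5 fell 3.58-fold and RPS6 2.92-fold, to 885 ± 71.9 from 2585 ± 715 CPM. Of 68 nuclear genes of oxidative phosphorylation 36 fell and 1 rose (35 and 1 adjusted over the list alone; camera adjusted p = 0.00056, adjusted p = 0.596 with an estimated correlation). Of 18 KLF and SP family genes, KLF4 included, 9 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0162, adjusted p = 0.207 with an estimated correlation), with KLF3 15.9-fold and KLF10 5.29-fold higher. The remaining lists had no camera call. Higher and lower members numbered 21 and 10 of 35 Wnt, BMP and TGF-β pathway genes (21 and 11 adjusted over the list alone; adjusted p = 0.185) and 15 and 9 of 33 unfolded protein and amino acid stress genes (15 and 9 adjusted over the list alone; adjusted p = 0.56). They numbered 12 and 10 of 29 NRF2 and antioxidant genes (12 and 10 adjusted over the list alone; adjusted p = 0.857) and 8 and 11 of 30 glycolysis and hypoxia genes (8 and 11 adjusted over the list alone; adjusted p = 0.154). They numbered 7 and 4 of 24 cholesterol synthesis genes (7 and 4 adjusted over the list alone; adjusted p = 0.782; median −0.07, mean 0.09), and 6 and 2 of 13 mitochondrially encoded genes (6 and 2 adjusted over the list alone; adjusted p = 0.32). Of the 13 lists called by camera, 6 held with an estimated correlation: cartilage (adjusted p = 0.0339), G2 and mitosis (0.00985), p53 targets (0.00142), epithelial (5.36e-06), endothelial (0.0174) and FOXO (0.0402).

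In all, 7916 of the 13239 tested genes were called between KLF4 and EGFP cells without IL-1β at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 4158 higher and 3758 lower. Of the genes named as higher or lower, all 7 KLF4 libraries lay beyond all 7 EGFP libraries except for ACAN, SOX9, MMP13, MCM2, ADAMTS5, MMP1 and CXCL8. On deposited TPM values limma called 4048 higher and 2225 lower. Against the 1 EGFP library with prefix 2, replicate 7, 95.7% of 7912 called genes kept their sign. Fits of replicates 1 to 3 and of replicates 4 to 7 alone gave 5027 and 8960 calls. The prefix as a term rests on that EGFP library and so mixes prefix with replicate set. With it 3773 genes were called, CXCL8 changed sign, and the calls of the KLF and SP and the oxidative phosphorylation lists were lost. The calls of ADAMTS5 (log2 −2.28, from −2.10) and ACAN (2.27, from 2.72) were lost at folds about as large, and those of SOX9 (0.13, from 0.37), MMP1 (−0.99, from −2.42), MMP13 (−0.69, from −2.01) and IL6 (−2.70, from −4.48) at smaller ones. The calls of SOX9, MMP1 and CXCL8 were also lost without the 5 libraries under 977736.5 counts, which include all 3 EGFP libraries of replicates 1 to 3, and on TPM values, where ADAMTS5 was not called either. ACAN, SOX9 and ADAMTS5 were not called in replicates 1 to 3 alone, nor SOX9 and CXCL8 in replicates 4 to 7 alone. With non-transduced cells as the control CXCL8 was not called (log2 −0.10, adjusted p = 0.894). LIF was called in opposite directions: higher in KLF4 cells when non-transduced cells were the control (log2 1.04), and lower than in EGFP cells in replicates 1 to 3 alone (log2 −1.20, adjusted p = 0.000142).

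**Figure D3:**
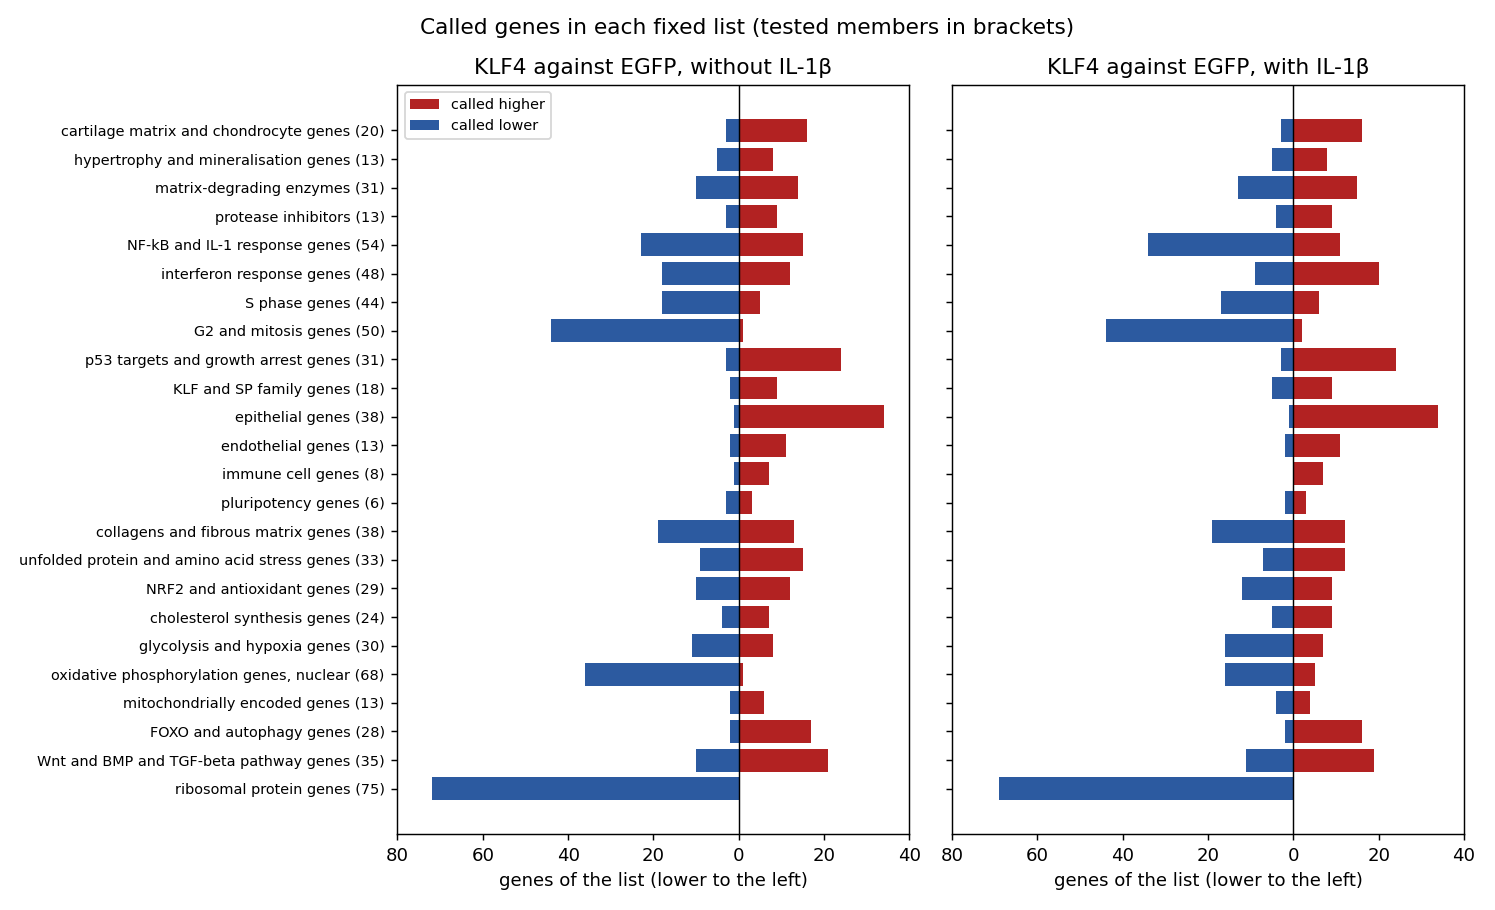
Number of members called higher (to the right) and lower (to the left) in KLF4 than in EGFP cells for each of the 24 gene lists, without and with IL-1β; the number of tested members is in brackets. The bars show 34 of 38 epithelial genes higher in both comparisons and 44 of 50 G2 and mitosis genes lower in both.

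The second comparison puts KLF4 against EGFP cells under IL-1β, and so asks which inflammatory and degrading transcripts differ in stimulated cells. Cytokines and chemokines were far lower with KLF4. IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002) was at 5.53 ± 4.68 CPM in KLF4 and 1038 ± 190 CPM in EGFP cells (n = 7 each), 248-fold lower (log2 −7.96, SE 0.43, adjusted p = 8.69e-22). CXCL8, a neutrophil chemokine (ENSG00000169429, chromosome 4, 73740519 to 73743716), was at 17.8 ± 7.64 against 1539 ± 281 CPM, 93.8-fold lower, and CCL2 at 0.714 ± 0.955 against 342 ± 57.7 CPM, 562-fold lower. CXCL2 was 177-fold lower and VCAM1 269-fold lower. CXCL6 had 1 count in KLF4 cells against 85.9 ± 14.8 CPM in EGFP cells, a ratio of 1423 (255 to 56242), while CCL7 and CCL11 had none and were at least 108-fold and 111-fold lower. PTGS2, the inducible enzyme of prostaglandin synthesis, was 12.6-fold lower, CCL20 5.37-fold lower and the cytokine LIF (ENSG00000128342, chromosome 22, 30240453 to 30246759) 11.1-fold lower, at 42.6 ± 6.80 against 467 ± 43 CPM. Of the 54 NF-κB and IL-1 response genes 34 fell and 11 rose (34 and 11 adjusted over the list alone), with a median of −1.55 (camera adjusted p = 1.64e-06). LCN2 went the other way, at 299 ± 77.1 against 0.330 ± 0.469 CPM.

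Under IL-1β the collagenase MMP13 was at 2.37 ± 1.58 CPM in KLF4 and 69.2 ± 11.3 CPM in EGFP cells, 24.9-fold lower (log2 −4.64, SE 0.28, adjusted p = 1.13e-19). The stromelysin MMP3 was 34.1-fold lower (0.622 ± 1.34 against 12.6 ± 4.76 CPM), MMP1 15.4-fold lower (113 ± 114 CPM in EGFP cells; libraries overlap only across the replicate sets, with 203.7 to 260.7 against 3.577 to 20.96 CPM in replicates 1 to 3 and 18.23 to 24.42 against 0 to 8.418 in replicates 4 to 7), and ADAMTS5 14.3-fold lower, whereas ADAMTS4 was 39.8-fold higher. Of the 31 matrix-degrading enzymes 15 rose and 13 fell (15 and 13 adjusted over the list alone; camera adjusted p = 0.77). TIMP1 was 18.6-fold and TIMP2 5.42-fold higher, among 9 inhibitors that rose and 4 that fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.0234, adjusted p = 0.232 with an estimated correlation). COL2A1 was at 24.7 ± 5.14 against 0.570 ± 0.733 CPM (57.2-fold higher), COMP 83.9-fold, COL11A2 95.2-fold, COL9A3 32.1-fold and ACAN 8.42-fold higher, and PRG4 at least 275-fold higher at 32.1 ± 8.19 CPM. SOX9 was 1.36-fold higher (adjusted p = 0.0119), a call that was lost in replicates 1 to 3 alone (log2 0.25, adjusted p = 0.517). Of the 20 cartilage genes 16 rose and 3 fell (16 and 3 adjusted over the list alone; camera adjusted p = 8.65e-06).

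Epithelial, growth and matrix genes also differed under IL-1β. KRT6A (2249 ± 126 CPM, at least 18114-fold), FLG (401 ± 25.1 CPM, at least 3292-fold), KRT17 (197-fold) and KRT16 (754-fold) were higher, as were PI16 (406 ± 113 CPM, at least 3183-fold) and the alpha globin gene HBA1, with 1157 ± 190 CPM against 3 counts, a ratio of 9618 (3291 to 46642). Again 34 of 38 epithelial genes rose and 1 fell (35 and 1 adjusted over the list alone), with a median of 4.90, or 4.81 with the members at 0 counts set to their bounds (camera adjusted p = 4.04e-18). Of the endothelial markers 11 rose and 2 fell (camera adjusted p = 0.00095), among them THBD (8.61-fold) and NOS3, endothelial nitric oxide synthase (at least 72.8-fold), and of the immune cell markers 7 rose (camera adjusted p = 0.000214). Of 50 G2 and mitosis genes 44 fell and 2 rose (camera adjusted p = 3.09e-14), CCNB1 by 3.70-fold, and of 31 p53 target and growth arrest genes 24 rose and 3 fell (camera adjusted p = 3.56e-05), CDKN1C by 90.6-fold to 1096 ± 102 CPM. FN1 was 8.83-fold, THBS1 18.9-fold and INHBA, a TGF-β family ligand, 29.9-fold lower, among 19 collagen and fibrous matrix genes that fell and 12 that rose (camera adjusted p = 0.000529, adjusted p = 0.191 with an estimated correlation; INHBA is not of this list). Of 75 ribosomal protein genes 69 fell, RPL5 by 3.05-fold (camera adjusted p = 3.78e-15, adjusted p = 0.306 with an estimated correlation), and of 30 glycolysis and hypoxia genes 16 fell and 7 rose (camera adjusted p = 0.0234, adjusted p = 0.289 with an estimated correlation). Of 28 FOXO and autophagy genes 16 rose and 2 fell (camera adjusted p = 0.00698). Of 48 interferon response genes 20 rose and 9 fell, with no camera call (adjusted p = 0.453), such as the regulator IRF7 (10.6-fold) and the peptide transporter TAP1 (2.98-fold). The counts for these lists were the same adjusted over the list alone, except 20 fibrous matrix genes lower.

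Under IL-1β 8043 of 13239 genes were called by edgeR, 4211 higher and 3832 lower, and limma on deposited TPM values called 3845 higher and 2292 lower. Apart from SOX9 and MMP1, all 7 KLF4 libraries lay beyond all 7 EGFP libraries for each gene named as higher or lower. Among libraries with prefix 3, 7 KLF4 against 5 EGFP, 6778 genes were called (3521 higher, 3257 lower). There were 5080 calls in replicates 1 to 3 alone and 8751 in replicates 4 to 7. Of the 12 lists called by camera 8 held with an estimated correlation: NF-κB (adjusted p = 0.00474), p53 targets (0.00474), G2 and mitosis (0.0118), epithelial (1.27e-06), cartilage (0.0207), endothelial (0.0133), immune cell (0.0398) and FOXO (0.0478). NRF2 genes had a median of 0.03 and mean of 0.38 but a downward camera direction, and mitochondrially encoded genes a median of 0.10 and a mean of −0.06, neither called.

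The effects of KLF4 without and with IL-1β were alike across genes. The log2 changes of the 13239 genes had a Pearson correlation of 0.93 and a Spearman correlation of 0.88; genes are not independent replicates, and the comparisons share no library. Of 6425 genes called in both, 6365 (99.07%) had the same sign, 3457 higher and 2908 lower, where independent lists would share 1323 and 1088. The Pearson correlation was 0.81 with the prefix as a term.

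The third comparison gives the IL-1β response of cells with the control vector, the background for the action of KLF4. Many chemokines and cytokines rose. CSF3, a granulocyte growth factor (ENSG00000108342, chromosome 17, 40015361 to 40017813), went from no count to 123 ± 16.6 CPM (n = 7), a rise of at least 1063-fold. CXCL8 rose 336-fold, from 7.40 ± 15.2 to 1539 ± 281 CPM (log2 8.39, SE 0.44, adjusted p = 8.86e-21), CXCL1 257-fold to 329 ± 90.7 CPM, CCL20 99.7-fold, CXCL6 43.4-fold, IL6 33.8-fold and LIF 8.93-fold. PTGS2 rose 40.2-fold, the protease inhibitor gene SERPINB2 (ENSG00000197632, chromosome 18, 63871692 to 63903888) 129-fold, and MT2A, a metallothionein, 5.60-fold to 2785 ± 731 CPM. Of 54 NF-κB and IL-1 response genes 36 rose and 2 fell (41 and 4 adjusted over the list alone), with a median of 1.65 (camera adjusted p = 3.45e-48). Of 31 matrix-degrading enzymes 10 rose (15 adjusted over the list alone; camera adjusted p = 7.1e-06): MMP13 rose 7.65-fold, MMP3 17-fold, the gelatinase MMP9 5.02-fold and ADAMTS5 2.62-fold. MMP1 (adjusted p = 0.0782) and ADAMTS4 (adjusted p = 0.626) were not called.

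Of 13 protease inhibitors 7 rose and 1 fell with IL-1β (7 and 1 adjusted over the list alone; camera adjusted p = 0.000119). Of 35 Wnt, BMP and TGF-β pathway genes 12 rose (16 adjusted over the list alone; camera adjusted p = 2.13e-05): the ligands INHBA 6.71-fold and WNT5A 2.30-fold, and GREM1, a BMP antagonist, 3.37-fold. Of 38 collagen and fibrous matrix genes 13 rose (18 adjusted over the list alone; camera adjusted p = 1.18e-06, adjusted p = 0.0585 with an estimated correlation), THBS1 by 2.51-fold. Of 48 interferon response genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.0032, adjusted p = 0.146 with an estimated correlation), IFI16 by 1.99-fold. Oxidative phosphorylation and ribosomal protein genes were shifted down by camera (adjusted p = 2.71e-06 and 1.51e-05; adjusted p = 0.531 and adjusted p = 0.62 with an estimated correlation), though only 1 oxidative phosphorylation gene was called. The ribosomal protein share of counts was 20.99% to 25.25% without and 13.73% to 21.4% with IL-1β in replicates 1 to 3, but 11.71% to 12.88% and 11.57% to 12.45% in replicates 4 to 7. The retinoid enzyme DHRS3 was 6.38-fold lower, at 8.94 ± 3.75 against 61.7 ± 16.5 CPM. COMP was 4.44-fold lower (adjusted p = 0.0337), at 0.251 ± 0.480 against 0.711 ± 0.809 CPM, a call that was lost at one total per library (adjusted p = 0.774), on TPM values (0.862) and in either replicate set alone. COL2A1, KLF4 and KLF2 were not called (adjusted p = 0.315, 0.137 and 0.942), though KLF4 was called higher without the shallow libraries (log2 1.24, adjusted p = 0.0131) and on TPM values (log2 0.59, adjusted p = 0.0399), nor was the cartilage list (adjusted p = 0.679; 1 of 20 members lower).

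In EGFP cells 1418 genes were called with IL-1β, 901 higher and 517 lower; 4 of the 8 called lists held with an estimated correlation, the NF-κB, matrix-degrading (adjusted p = 0.00585), protease inhibitor (0.0488) and pathway (0.00367) lists. The balance depended on the scaling: edgeR with DESeq2 size factors called 743 higher and 657 lower, DESeq2's own test 879 and 938, and limma on deposited TPM values 511 and 106. With prefix 2 only, 93.3% of 1415 called genes kept their sign in replicates 1 and 2 with IL-1β against replicate 7 without it. This mixes IL-1β with the replicate sets. Replicates 1 to 3 alone gave 913 calls and replicates 4 to 7 alone 2450. With the prefix as a term 122 genes were called, among them 22 NF-κB genes that rose, while the interferon list was not called, and the oxidative phosphorylation and ribosomal protein lists turned upwards. The calls of CCL20 (log2 8.75, from 6.64), COMP (−4.63, from −2.15) and GREM1 (2.29, from 1.75) were lost at larger folds, and those of MMP3 (2.81, from 4.09), ADAMTS5 (0.58, from 1.39), WNT5A (0.87, from 1.2) and IFI16 (−0.54, from −0.99) at smaller ones. The ADAMTS5 call was also lost in the fit of only the groups compared (adjusted p = 0.114), on TPM values (0.0528), without the shallow libraries (0.0829) and at one total per library (0.069), and that of MMP3 in replicates 1 to 3 alone (0.117). MMP1 was called with the replicate number as a block (log2 1.74), without the shallow libraries (log2 4.08) and in either replicate set alone.

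Non-transduced cells show the IL-1β response without any vector. CXCL8 rose 912-fold to 1798 ± 251 CPM from 1.91 ± 1.56 (n = 7 each), CXCL1 682-fold to 553 ± 86.6 CPM (ENSG00000163739, chromosome 4, 73869393 to 73871308), IL6 105-fold to 703 ± 86.4 CPM, SERPINB2 609-fold, and CSF3 from no count to 134 ± 14 CPM, at least 1367-fold. MMP13 rose 11.8-fold to 68.4 ± 9.15 CPM and MMP3 33.6-fold. COL2A1 had 3 counts with IL-1β and 50 without, a ratio of 12.1 (3.9 to 60.5), and COMP was 3.87-fold lower. The COMP call was lost on TPM values (log2 −0.09, adjusted p = 0.951), at one total per library (0.111) and in replicates 1 to 3 (0.305) and 4 to 7 (0.128) alone, and that of COL2A1 on TPM values (0.346) and in replicates 1 to 3 alone (0.127). KLF4 was not called (log2 −0.94, adjusted p = 0.0761), but was called lower with the replicate number as a block (−0.97), with a term for the replicate sets (−0.93), without the shallow libraries (−0.93), at one total per library (−1.55) and in replicates 4 to 7 alone (−1.12). Of 54 NF-κB and IL-1 response genes 42 rose and 1 fell (45 and 1 adjusted over the list alone; camera adjusted p = 2.3e-81), and of 31 matrix-degrading enzymes 13 rose and 1 fell (13 and 2 adjusted over the list alone; camera adjusted p = 2.86e-05). Protease inhibitors (5 higher, 1 lower; 7 and 2 adjusted over the list alone) and Wnt, BMP and TGF-β pathway genes (11 and 2; 12 and 2 adjusted over the list alone) were also called upwards. Calls of the collagen (adjusted p = 0.141 with an estimated correlation), glycolysis (0.141), NRF2 (0.186), interferon (0.172) and S phase (0.173) lists were lost with an estimated correlation. The median and mean of the p53 list (−0.12 and −0.09) had the opposite sign to its camera direction, and the hypertrophy list had a median of −0.22 and a mean of 0.27, neither called.

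In non-transduced cells 2175 genes were called with IL-1β, 1145 higher and 1030 lower by edgeR. All unstimulated libraries have prefix 1 and all stimulated ones prefix 2, so no prefix holds both. With the prefix as a term, estimated from the EGFP libraries, 154 genes were called, COL2A1 changed sign, and the calls of CSF3 (log2 11.80, the same as without the term), COMP (−1.51, from −1.95) and MMP3 (2.77, from 5.07) were lost. The replicate sets 1 to 3 and 4 to 7 alone gave 410 and 3572 calls.

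In cells with KLF4 fewer genes were called with IL-1β. CXCL8 rose 8.90-fold but to only 17.8 ± 7.64 CPM from 1.79 ± 0.705 (n = 7 each; log2 3.15, SE 0.47, adjusted p = 3.51e-05), CXCL1 7.31-fold to 19.6 ± 13.4 CPM and CCL20 19.5-fold to 4.43 ± 3.29 CPM. The hyaluronan-binding gene TNFAIP6 rose 13.1-fold and the adhesion receptor ICAM1 2.46-fold, to 142 ± 18.8 CPM. IL6 (5.53 ± 4.68 against 1.63 ± 0.993 CPM; adjusted p = 0.294), PTGS2 (adjusted p = 0.206), MMP13 (adjusted p = 0.859) and LIF (adjusted p = 0.951) were not called, but IL6 was called higher on TPM values (log2 1.2, adjusted p = 0.0367) and PTGS2 in replicates 4 to 7 alone (log2 1.42, adjusted p = 0.02). The calls of TNFAIP6 (log2 4.41, adjusted p = 0.0598), ICAM1 (1.09, 0.126) and CCL20 (4.21, 0.245) were lost in replicates 1 to 3 alone. That of ICAM1 was also lost on TPM values (log2 0.51, adjusted p = 0.779). Of 54 NF-κB and IL-1 response genes 13 rose and 1 fell (23 and 2 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 4.77e-18, and adjusted p = 2.46e-06 with an estimated correlation). S phase (adjusted p = 0.235 with an estimated correlation), collagen (0.48) and mitochondrially encoded genes (0.48) were called by camera but not with an estimated correlation. In all 93 genes were called, 64 higher and 29 lower, of 1410 at an unadjusted p under 0.05; 188 were called with the replicate number as a block, 192 by DESeq2, and 146 higher and 27 lower by limma on deposited TPM values. All unstimulated KLF4 libraries have prefix 2 and all stimulated ones prefix 3; with the prefix as a term 3 genes were called, and the calls of CXCL8 (log2 2.73, from 3.15), CCL20 (3.56, from 4.28) and ICAM1 (0.84) were lost. Replicates 1 to 3 alone gave 15 calls and replicates 4 to 7 alone 417, and without replicate 3 of the stimulated cells 58 genes were called.

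The difference between the responses of KLF4 and EGFP cells was tested directly, as an interaction. MMP13 rose with IL-1β by 2.93 on the log2 scale in EGFP cells and by 0.31 in KLF4 cells, a difference of −2.62 (SE 0.46, adjusted p = 0.000159). The differences were −5.24 for CXCL8 (SE 0.74, adjusted p = 2.28e-06), −5.13 for CXCL1, −4.19 for PTGS2, −3.48 for IL6 (SE 0.80, adjusted p = 0.00454), −3.09 for LIF, −2.17 for NAMPT and −1.70 for INHBA. CSF3 had a fitted difference of −9.52, which depends on the prior count because EGFP cells without IL-1β had no count; its call was lost at one total per library (−6.30, adjusted p = 0.117). SERPINB2 (−6.26) and PI3, the elastase inhibitor elafin (−5.32; ENSG00000124102, chromosome 20, 45174902 to 45176544), were already high in KLF4 cells without IL-1β, at 184 ± 26.5 and 816 ± 237 CPM, and were at 309 ± 17.4 and 1303 ± 183 CPM with it. DHRS3 went the other way (2.89, SE 0.30, adjusted p = 1.37e-09). MMP3 (−4.12, SE 1.51, adjusted p = 0.114) and CCL20 (−2.35, SE 1.27, adjusted p = 0.335) were not called, but both were called with a smaller response on TPM values (−1.82, adjusted p = 1.33e-05, and −2.18, adjusted p = 0.000372), and MMP3 without the shallow libraries (−6.47, adjusted p = 0.00602).

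Of 54 NF-κB and IL-1 response genes 20 had a lower and 1 a higher response in KLF4 cells (24 and 2 adjusted over the list alone), with a median difference of −0.98 (camera adjusted p = 6.91e-22, and adjusted p = 3.14e-07 with an estimated correlation). The Wnt, BMP and TGF-β pathway list was also lower (7 members; 16, with 2 higher, adjusted over the list alone; camera adjusted p = 8.83e-05, and adjusted p = 0.00639 with an estimated correlation). Further camera calls were lost with an estimated correlation: matrix-degrading enzymes (5 of 31 lower, 7 adjusted over the list alone; adjusted p = 0.219), protease inhibitors (0.28), interferon (0.219), collagen (0.438), NRF2 (0.438), oxidative phosphorylation (0.511), mitochondrially encoded (0.511) and ribosomal protein genes (0.533). The pluripotency list had a median of 0.67 and a downward camera direction and was not called. In all 614 genes differed, 222 with a higher and 392 with a lower response, 999 with the replicate number as a block; DESeq2's own test called 435 and 464. Replicates 1 to 3 alone gave 113 calls. CXCL8 (log2 −1.82), CSF3 (−4.61), MMP13 (−2.68) and INHBA (−1.04) were not among them. Replicates 4 to 7 alone gave 1241 calls. No prefix holds all 4 groups; with the prefix as a term 57 genes were called, 9 NF-κB genes were lower, PTGS2 was not called (−3.76, from −4.19), and the ribosomal protein list turned downwards.

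**Figure D4:**
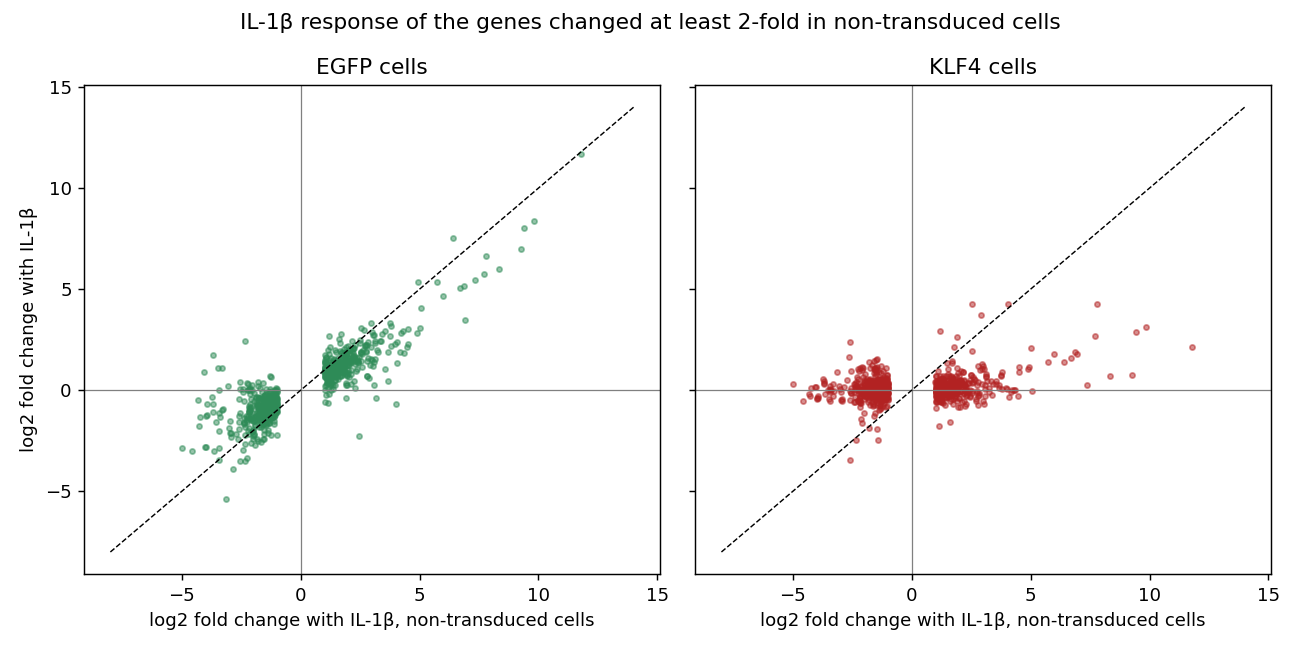
Log2 change with IL-1β in EGFP cells (left, vertical axis) and in KLF4 cells (right, vertical axis) against that in non-transduced cells (horizontal axis) for 796 genes, each point a gene; the dashed line marks equality. The slope was 0.65 in EGFP cells and 0.10 in KLF4 cells.

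The genes that IL-1β raised or lowered in non-transduced cells were then followed in the comparison of KLF4 with EGFP cells, whose libraries are separate. Of the 1145 raised genes, 665 (58.1%) were lower and 209 higher with KLF4 under IL-1β, against 27.2% lower among 11064 other genes (odds ratio 3.70, two-sided Fisher's exact test p = 7.11e-95; genes are not independent), and their median was −0.60 (camera p = 1.38e-12, and p = 0.000142 with an estimated correlation). Of the 1030 lowered genes 578 (56.1%) were higher, against 30.9% of the others (odds ratio 2.85, two-sided Fisher's exact test p = 7.59e-57; median 0.75, camera p = 3.39e-08, and p = 0.0145 with an estimated correlation). Without IL-1β the raised genes split into 415 lower and 396 higher, with a median of −0.01, and the lowered genes into 285 lower and 406 higher, with a median of 0.22; camera called neither set. Raised genes were more often lower than others (36.2% against 27.6%, two-sided Fisher's exact test p = 1.95e-09). The share that was higher, 34.6% against 30.3%, was not tested. Of those raised at least 2-fold 31.3% were lower and 42.5% higher (two-sided Fisher's exact test for lower p = 0.26, median 0.32). Lowered genes were more often higher (39.4% against 30.3%, two-sided Fisher's exact test p = 3.81e-09; 27.7% against 27.6% lower), and of the 438 lowered at least 2-fold the median was 0.62 and camera called them upwards. With the prefix as a term only 126 genes were raised in non-transduced cells; in that smaller set and that model the median without IL-1β was 0.95 and camera called it upwards.

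Last, EGFP cells were compared with non-transduced cells to see what the vector itself did. Without IL-1β the cell cycle inhibitor CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687337) was 4.4-fold higher, at 250 ± 33.3 against 56.3 ± 9.16 CPM (n = 7 each; adjusted p = 1.91e-15). The p53 targets BTG2 (6.23-fold) and MDM2 (3.46-fold), the cytokines IL11 (4.4-fold) and IL6 (4.57-fold, overlapping libraries) were higher too. Of 31 p53 target and growth arrest genes 13 rose and 1 fell (15 and 2 adjusted over the list alone; camera adjusted p = 2.15e-09, and adjusted p = 0.000149 with an estimated correlation). Of 54 NF-κB and IL-1 response genes 18 rose (23, with 1 lower, adjusted over the list alone; adjusted p = 0.000377 with an estimated correlation), and of 30 glycolysis and hypoxia genes 14 rose and 1 fell (18 and 1 adjusted over the list alone; adjusted p = 0.00101 with an estimated correlation). KLF4 was not called (log2 −0.53, SE 0.38, adjusted p = 0.446), but was called lower in replicates 4 to 7 alone (log2 −1.08, adjusted p = 0.0111). Ribosomal protein genes were shifted up (11 of 75, 55 adjusted over the list alone; adjusted p = 0.391 with an estimated correlation; their share of counts was 20.99% to 25.25% in EGFP against 14.57% to 17.02% in non-transduced libraries of replicates 1 to 3, but 11.71% to 12.88% against 11.03% to 12.51% in replicates 4 to 7), as were oxidative phosphorylation genes (11 of 68, 19 adjusted over the list alone; adjusted p = 0.4 with an estimated correlation). In all 909 genes were called by edgeR, 517 higher and 392 lower, and 1590 with the replicate number as a block; limma on deposited TPM values called 160 higher and 499 lower. Within prefix 1, 6 EGFP against 7 non-transduced libraries gave 252 calls (125 higher, 127 lower), and replicates 1 to 3 and 4 to 7 alone gave 1467 and 1389.

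With IL-1β the vector gave a like picture for the p53 list, of which 15 members rose (17, with 3 lower, adjusted over the list alone; camera adjusted p = 4.35e-17, and adjusted p = 2.09e-07 with an estimated correlation). BTG2 was 7.78-fold higher, at 23.9 ± 7.04 against 2.95 ± 0.836 CPM (n = 7 each), CDKN1A 3.52-fold, MDM2 2.88-fold and the coagulation factor gene F3 4.07-fold higher. Glycolysis and hypoxia genes (11 higher, 1 lower; 17 and 1 adjusted over the list alone; adjusted p = 0.00548 with an estimated correlation) and cholesterol synthesis genes (3 higher; 8, with 1 lower, adjusted over the list alone; adjusted p = 0.0449 with an estimated correlation) were called upwards. The NF-κB list was not (8 higher, 10 lower; 8 and 15 adjusted over the list alone; camera adjusted p = 0.117). KLF4 was 2.43-fold higher, at 5.12 ± 3.08 against 1.96 ± 1.09 CPM (adjusted p = 0.027), a call that was lost on TPM values, at one total per library and in replicates 4 to 7; the MDM2 call was lost on TPM values too (adjusted p = 0.147). In all 875 genes were called by edgeR, 492 higher and 383 lower, and 1367 with the replicate number as a block. Within prefix 2, 2 EGFP libraries, both of replicates 1 to 3, against 7 non-transduced libraries of both sets gave 924 calls (618 higher, 306 lower), and replicates 1 to 3 and 4 to 7 alone gave 340 and 1379.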

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

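The tests of transcript length, of basal keratinocyte RNA, of depth within each stimulation, of unstimulated or mislabelled libraries and of the library-name prefix, and the counts of balanced splits, were chosen only after the result was seen; the others were written down first.

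In 8 of 114 series of 7 libraries a single value stood far from the other 6, where chance gives 5.7. In CPM these were PRG4 in replicate 6 of stimulated non-transduced cells (0.6343, others 0), COMP in replicate 5 of stimulated EGFP cells (1.252, others up to 0.5029), MMP3 in replicate 1 of unstimulated KLF4 cells (1.88, others up to 0.484) and in replicate 2 of stimulated KLF4 cells (3.577, others up to 0.7781), and MMP13 in replicate 3 of unstimulated non-transduced cells (9.81, others 4.536 to 6.699). The rest were CXCL8 in replicate 3 of unstimulated EGFP cells (41.78, others up to 4.218), CCL20 in replicate 5 of those cells (0.7568, others 0) and the total count of replicate 7 of stimulated EGFP cells (7768256, others 1563239 to 4070068). On CPM without TMM scaling, the scale used first and replaced after both were seen, 9 gene series stood out, 6 of them among the 7 gene series above. The 3 found only there were ACAN in replicate 1 of unstimulated non-transduced cells (5.353), MMP13 in replicate 2 of stimulated non-transduced cells (47.98) and ADAMTS4 in replicate 5 of stimulated EGFP cells (1.279).

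The response to IL-1β differed between KLF4 and EGFP cells for 614 genes, by a test of the difference itself. Among named genes the log2 difference was −2.62 for MMP13, −3.48 for IL6, −5.24 for CXCL8, −4.19 for PTGS2, −3.09 for LIF, −9.52 for CSF3, −6.26 for SERPINB2 and −5.32 for PI3. It was 3.16 for GIPR, 3.00 for CDK18, 2.89 for DHRS3 and 2.88 for RHPN1, all of which fell with IL-1β in EGFP cells.

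The first pattern is the smaller response to IL-1β in KLF4 cells. Noise or low depth would leave the slopes alike, but the slope in KLF4 cells was 0.15 of that in EGFP cells (0.10 to 0.19 over 2000 resamples of genes). It was taken over 796 genes changed at least 2-fold in non-transduced cells. In KLF4 cells 13 NF-κB and IL-1 response genes still rose, which libraries that were never stimulated would not show. But KLF4 libraries have prefix 2 without and 3 with IL-1β, so a prefix difference could give these calls too. With the prefix as a term the NF-κB list was still lower in the difference (camera adjusted p = 1.04e-22). Open is how far genes were already at the stimulated level, since 31% of 306 raised genes with a smaller response, 95 genes, had at least the stimulated EGFP level in KLF4 cells without IL-1β. A candidate explanation is a lower receptor transcript: IL1R1 was lower by −3.25 on the log2 scale without IL-1β (3.36 against 25.9 CPM, adjusted p = 5.86e-15) and by −4.47 with it (adjusted p = 2e-20), while IL1RAP differed by −1.06 and −1.07, but no receptor protein was measured and the KLF4 vector itself remains an untested biological explanation.

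The second pattern is that more genes had a count in KLF4 libraries, for which the KLF4 vector is the biological explanation the design gives. Thinned to 1012428 counts, without the shallower libraries, KLF4 libraries had 1983 more genes than EGFP libraries over both stimulations, though not every KLF4 library exceeded every EGFP library; within each stimulation they did (6 KLF4 and 4 EGFP libraries without IL-1β, the latter all of replicates 4 to 7, and 6 and 7 with it), with means at least 1816.6 genes apart (two-sided exact permutation test p = 0.00476 without and p = 0.000583 with IL-1β), which argues against depth. Stray reads would spread thinly, but 100 genes held 75.7% or more of the counts in genes silent in the other cells. Such genes with a KLF4 count numbered 5089 without and 4369 with IL-1β. A share of counts held by 100 genes cannot say how the many others came by theirs, so stray reads stay open for those. HBB was at 1.13% of HBA2, which argues against red blood cells. RNA of basal keratinocytes stays open, since KRT14, the higher of KRT5 and KRT14, was at 12.9% of KRT6A, between both bounds set for that test (KRT14 at 275 and 324 CPM, KRT5 at 29.8 and 27.5, KRT1 at 0.229 and 0.338).

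The third pattern is the gap between replicates 1 to 3 and 4 to 7 in every group, with 5358 genes different in edgeR, 2792 higher and 2566 lower in replicates 4 to 7. With libraries thinned to at most 1012428 counts 4507 genes still differed. In that fit the 5 shallower libraries, all of replicates 1 to 3, kept their lower totals, so it cannot settle the part of depth. In limma 4104 genes differed after centring by transcript length and 5050 after centring by GC content, of 5700. These counts argue against length or GC content as the whole cause. Length still followed the difference across genes (Spearman correlation 0.46; genes are not independent) and may account for a part of it; GC content had −0.28. The labels do not say what the sets are, and no biological explanation was tested.

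Other splits of the libraries into groups of the same size were drawn, 100 for each comparison with the real one counted. They were fitted with only the groups compared. The limit set was fewer than 5 splits with as many calls as the real one. For KLF4 against EGFP without IL-1β 1 split gave as many genes as the real 6470 (highest other 199), and with IL-1β 1 split as many as 6934 (highest other 2779). For IL-1β in EGFP cells 3 splits reached the real 483, the highest with 1416, and for IL-1β in non-transduced cells 1 split reached 2839 (highest other 409). For IL-1β in KLF4 cells 2 splits reached 140 (highest other 152), for the difference of responses 2 reached 420 (1545), and for the vector 2 reached 316 without IL-1β (481) and 1 reached 953 with it (281). All 8 counts thus met the limit. For IL-1β in EGFP and KLF4 cells, the difference and the vector without IL-1β, other splits reached the real count. Chance is not excluded for these by splits that ignore the replicate sets. Among splits with as many libraries of replicates 1 to 3 on each side as the real one, only the real one reached its count in each comparison. The split with 1416 genes put all 6 libraries of replicates 1 to 3 on one side, which points to a structure of the samples; with the replicate number as a block IL-1β in EGFP cells called 2023 genes and the difference 999. Besides the real one, 1 to 5 of the splits of each comparison of 2 groups part all 7 same-numbered pairs, too few to decide more; they called 0 genes in edgeR, the only tool run on them, and none was sought for the difference of responses.

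For the number of called lists, 3 splits reached the real 13 for KLF4 without IL-1β (highest other 13), which met the same limit of fewer than 5. Chance cannot be excluded for the number of lists with KLF4 under IL-1β (10 splits reached 11, highest other 12) and for IL-1β in EGFP cells (5 reached 10, highest 11). Nor can it be for IL-1β in non-transduced cells (13 reached 9, highest 14) and for the difference of responses (23 reached 9, highest 12). Those splits ignore the replicate sets. Among the splits with as many libraries of replicates 1 to 3 on each side as the real one, 4 of 46 reached the real number for KLF4 under IL-1β, 1 of 38 and 2 of 49 for IL-1β in EGFP and non-transduced cells, and 4 of 19 for the difference, so for IL-1β in EGFP and non-transduced cells the answer depends on which splits are drawn.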

How the results depend on the processing

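The term for replicates 1 to 3 against 4 to 7 and either set alone were tests chosen after the result was seen; the others were planned. Of the values of named genes, 1977 kept direction and side of the threshold, 62 lost and 20 gained a call in the same direction and 22 changed sign; of the gene counts 198 stayed within 1.5 times of the main one and 47 did not, of the counts of list members 237 and 19. Of the 22, CXCL8 for KLF4 against EGFP without IL-1β (5.62) and COL2A1 for IL-1β in non-transduced cells (1.32) were called before and not with the library-name prefix as a term, and LIF for KLF4 without IL-1β was called only with non-transduced cells as the control (1.04, from −0.38). The others were called on neither side: with the prefix as a term KLF2 for KLF4 without IL-1β (−0.83), COL2A1 for IL-1β in EGFP cells (2.29), and LIF (−0.04) and MMP13 (−0.17) for IL-1β in KLF4 cells; on TPM values KLF2 (0.29) and COL2A1 (0.04) in EGFP and MMP13 (−0.01) in KLF4 cells; without the shallow libraries MMP3 (0.22) and LIF (0.08) for KLF4 without IL-1β and LIF in KLF4 cells (−0.04); at one total ADAMTS4 in EGFP (−0.11) and MMP13 in KLF4 cells (−0.15); with non-transduced cells as the control KLF2 without IL-1β (−0.09); in replicates 1 to 3 KLF4 (−0.03) and KLF2 (0.94) for IL-1β in EGFP cells, MMP13 in KLF4 cells (−0.29) and KLF4 for the vector without IL-1β (1.58); in replicates 4 to 7 LIF for KLF4 without IL-1β (0.13) and for IL-1β in KLF4 cells (−0.08). Without IL-1β the median of the genes raised by IL-1β turned to 0.95 with the prefix and 0.32 for 2-fold changes, and that of the lowered genes to −0.33 with the prefix. Unless said otherwise, the cause of a change was not tested. SOX9, MMP1 and CXCL8 lost their calls between KLF4 and EGFP cells without IL-1β when the 5 shallow libraries were left out (log2 0.20, −0.72 and −0.59) and kept them at one total per library; leaving out the shallow libraries removes all EGFP libraries of replicates 1 to 3 without IL-1β. MMP1 kept its call in replicates 1 to 3 and in replicates 4 to 7 alone, with all EGFP libraries above all KLF4 libraries within each set (57.26 to 116.1 against 11.07 to 16.12 CPM, and 4.541 to 8.917 against 0.242 to 2.362), so its loss goes with the unequal share of the sets in the groups left.

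With the prefix as a term, genes called numbered 3773 for KLF4 against EGFP without IL-1β, 122, 154 and 3 for IL-1β in EGFP, non-transduced and KLF4 cells, 57 for the difference of responses and 438 for EGFP against non-transduced cells with IL-1β; called lists in the difference fell to 6 from 10, and the correlation of KLF4 effects without and with IL-1β to 0.81 from 0.93. Few libraries, all of EGFP cells, separate prefix from group, and changes under this term may come from the replicate sets. The prefix effect itself had 0 genes in edgeR (981 at an unadjusted p under 0.05; not run in another tool). Within prefix 1, EGFP against non-transduced cells without IL-1β gave 252 genes; within prefix 2, KLF4 against EGFP without IL-1β gave 4342 and IL-1β in EGFP cells 341, with fewer samples.

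With the replicate number as a block, 188 genes were called for IL-1β in KLF4 cells, 999 for the difference of responses, and 1590 and 1367 for EGFP against non-transduced cells without and with IL-1β. For KLF4 against EGFP, where the numbers do not pair the libraries, the block gave 8284 and 8462. It added a call of MMP1 for IL-1β in EGFP cells, of KLF4 as lower (−0.97) in non-transduced cells and of the cholesterol list in EGFP cells and changed no other call of a list. A term for the replicate sets gave 2198 and 227 for IL-1β in EGFP and KLF4 cells, 1140 for the difference, and 1756 and 1538 for the vector.

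Replicates 1 to 3 alone, with fewer samples, called 5027 and 5080 for KLF4 without and with IL-1β, 913, 410 and 15 for IL-1β in EGFP, non-transduced and KLF4 cells, 113 for the difference, and 1467 and 340 for the vector. Replicates 4 to 7 alone called 2450, 3572 and 417 for IL-1β, 1241 for the difference, and 1389 and 1379 for the vector. Fits of only the groups compared called 483 and 140 for IL-1β in EGFP and KLF4 cells and 316 for the vector without IL-1β. Without the shallow libraries, which leaves only replicates 4 to 7 of the EGFP cells without IL-1β against groups with both sets, 2162 were called for IL-1β in EGFP cells, 936 for the difference and 1487 for the vector with IL-1β; at one total per library, with fewer counts, the last 2 were 383 and 547.

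DESeq2 size factors moved the median log2 change of all genes by at most 0.08; on TPM values, looked at after the result was seen, it was 0.16 for KLF4 without IL-1β, 0.10 for IL-1β in EGFP cells and −0.20 for the vector without IL-1β, against 0.01, −0.02 and −0.00 on counts. DESeq2 called 192 for IL-1β in KLF4 cells. On TPM values limma called 617, 688 and 173 for IL-1β in EGFP, non-transduced and KLF4 cells, 221 for the difference and 189 for the vector with IL-1β. Leaving out each library in turn gave 7575 to 7972 and 7748 to 7994 for KLF4 without and with IL-1β, 1171 to 1789, 1854 to 2106 and 58 to 101 for IL-1β in EGFP, non-transduced and KLF4 cells (58 without replicate 3 of the stimulated KLF4 cells), 468 to 752 for the difference, and 631 to 1052 and 639 to 884 for the vector. With an estimated correlation, 6 lists were called for KLF4 without IL-1β, 4 and 4 for IL-1β in EGFP and non-transduced cells and 2 for the difference.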

Other observations

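In this part single lists were compared with other splits, and genes chosen, after the results were seen. DHRS3, a retinol-pathway reductase (ENSG00000162496, chromosome 1, 12567910 to 12618210), fell with IL-1β in EGFP cells, from 61.7 ± 16.5 to 8.94 ± 3.75 CPM, and was at 21.4 ± 5.71 CPM without and 25.3 ± 3.68 CPM with it in KLF4 cells (SD, n = 7). Its response differed between both cells by 2.89 on the log2 scale. Of 13 hypertrophy and mineralisation genes 8 were higher and 5 lower with KLF4 under IL-1β (8 and 5 adjusted over the list alone), the same numbers as without it, and the list was called in neither comparison. MMP1 varied widely, with an SD near its mean in EGFP cells (38.9 ± 43.6 CPM without and 113 ± 114 CPM with IL-1β). It was lower in replicates 4 to 7 than in 1 to 3 (log2 −3.23 over all groups).

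With KLF4 genes of several lineages rose side by side: keratins, alpha globin, lymphocyte and myeloid markers, endothelial junction genes and TRH. Of 100 splits only the real one gave a camera p as small for the epithelial, cartilage and p53 lists in both comparisons of KLF4 with EGFP. For the first 2 lists this is no independent support. Of their members 6 and 1 without and 9 and 2 with IL-1β had no count in one group, favouring the real split. For the ribosomal protein list 28 splits without and 16 with IL-1β gave a p as small, and for oxidative phosphorylation 67 without it. Camera's p at a preset correlation says little about those lists. The share of counts in ribosomal protein genes itself was lower in all 7 KLF4 than in all 7 EGFP libraries, at 5.818% to 9.39% against 11.71% to 25.25% without IL-1β and 5.853% to 7.861% against 11.57% to 21.4% with it.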
